A study of Gallus gallus with 13 samples.

How the data were processed

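Single nuclei from embryonic chicken eyes, whole ones per the submitters, were profiled with the Parse Biosciences split-pool whole transcriptome kit, chemistry version 1, in 7 sublibraries. The submitters list 13 sequencing samples, since 3 of the sublibraries were sequenced in 3 lanes. Every sample held nuclei of all 4 conditions, so the samples form 1 group and the conditions were told apart by the barcode well of each nucleus, as the labels assign it. Each condition was 1 pool of eyes from 3 embryos. The names of E4 and E5 in the metadata contain RPE, those of RET and RET_FGF2 do not, and whether the E4 and E5 eyes were dissected further is not given in the sources used here. If they were, the shares of classes would not be those of a whole eye, nor comparable with the operated pools. The conditions were embryonic day 4 (E4), embryonic day 5 (E5), E4 collected 6 h after retinectomy (RET), and E4 collected 6 h after retinectomy with about 20 heparin-coated acrylic beads placed in the eye (RET_FGF2). Those beads had been soaked in 4 µl of bovine FGF2 at 250 ng/µl.

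The deposited matrix holds raw UMI counts of transcripts per nucleus and gene, with no normalization by the authors. It covers 58747 nuclei and 30108 genes, of which 14249 carry a gene symbol, and 338748300 UMIs in total. The sum over genes equalled the transcript count given in the metadata for all 58747 nuclei. The genome build was GRCg7b per the submitters. The aligner and the counting tool are not given in the sources used here. Of all nuclei, 32089 came from the 27 wells that the labels give to a condition, and the remaining 26658 nuclei were not analysed here beyond their count. Coordinates come from the RefSeq annotation of GRCg7b, matched by symbol, and symbols listed there more than once were given no place.

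Nuclei needed at least 500 UMIs and 300 genes and under 5% mitochondrial UMIs, which left 31332 and removed 757. The sublibraries held 4326 to 4566 of the kept nuclei each. Doublets were predicted within each sublibrary from simulated doublets, 2 per nucleus, with 60 neighbours and an assumed doublet rate of 0.06. The automatic threshold between the modes of the simulated scores called almost no nuclei, so nuclei with a score above 0.2 were removed. That limit was chosen after the distribution of scores was seen. Of the simulated doublets, 15.26% to 18.97% per sublibrary scored above it, so most of them would have been kept. It removed 4.42% of E4, 3.99% of E5, 3.34% of RET and 3.12% of RET_FGF2 nuclei. Counts were log-normalized to 10000 per nucleus, 2000 variable genes and 30 principal components were taken, and a graph of 15 nearest neighbours was clustered with Leiden at resolution 1, which gave 30 clusters. A cluster took the name of the marker list with the largest share of raised markers, with at least 3 raised by 0.5 on the log2 scale, out of 20 marker lists. The names therefore end in "like". The 4 clusters left unnamed had too few raised markers or a median doublet score above 0.1. Neural retina-like nuclei are the union of progenitor, ganglion cell, photoreceptor precursor and horizontal or amacrine clusters. Periocular mesenchyme was compared within cluster 2 alone, since cluster 14 had a marker of another class among its 10 leading genes and cluster 13 was mostly from E5. That choice was made after the clusters were seen.

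With 1 pool per condition there is no replicate of embryos, so no test, p-value or count of differing genes is given. UMIs were summed over the nuclei of a class in each pool and scaled to CPM, the counts per 10⁶ UMIs of that sum. The log2 ratio of CPM between pools, with a prior count of 0.5, is given with the exact conditional binomial 95% interval, CPM with exact Poisson intervals, and shares of nuclei with Clopper-Pearson intervals. All of these cover counting error only, not the difference between embryos, wells or operations. The 7 sublibraries are technical divisions of the same pools, and the number of them with the same direction is given as such. For genes at 0 on one side the floor is 3 counts over the summed class.

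The comparisons were E5 over E4, RET over E4, RET_FGF2 over RET and RET_FGF2 over E4 within each class, and lens fiber-like over lens epithelium-like nuclei within a pool. The marker lists, the comparisons, the rule for named genes, most of the alternatives and 24 gene lists were fixed before the data were examined. These lists cover FGF and ERK feedback targets, immediate early genes, heat shock and stress chaperones, hypoxia and glycolysis, wound matrix and adhesion, YAP and TEAD targets, inflammation, p53 and damage response, melanin pigment genes, eye field and retinal progenitor regulators, retinal neurogenesis, S phase genes, G2 and M phase genes, cell cycle exit, crystallins, lens fiber membrane and cytoskeleton, lens transcription factors, organelle clearance and autophagy, genes linked to inherited cataract, Wnt targets, Notch pathway, BMP targets, heterochronic genes, and fibrillar and basement membrane collagens. A list member counted as measured with at least 20 UMIs over both sides, and a list needed 3 measured members. For each list the median log2 ratio of its measured members was taken, with a 95% interval from 1000 Poisson resamples of the counts. Its percentile among 10000 random lists of the same size, matched on mean expression in 20 bins, was also computed. So was the number of members at least 1.5-fold higher or lower. The text prints a part of these values for each list. Lists share members with the markers that name the classes: pigment genes name RPE-like clusters, and crystallins and fiber genes name lens-like ones, so those lists are read between pools of the same class and not as evidence of identity.

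Genes were named by rule: a symbol, no mitochondrial gene, at least 50 UMIs over both sides, at least 50 CPM on the higher side and the same direction in at least 6 of 7 sublibraries. From these the 10 highest and the 10 lowest were taken, ranked by the bound of the interval nearest 0, and the text names a part of them. Members of a list may be named as examples of it. Genes singled out in another class than the one that ranked them were chosen after their values were seen.

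The alternatives were TMM factors for the sums (edgeR 4.0.16 in R 4.3.3), a minimum of 2000 UMIs, predicted doublets kept, Leiden at resolution 2, sublibraries 1 to 3 or 4 to 7 alone, and the mean of CPM per nucleus. With predicted doublets kept, all nuclei were clustered and named anew, so the members of each class changed. A cluster of 809 nuclei with ASL1 and MIP among its leading genes and a median doublet score of 0.1423 then stayed unnamed. The lens fiber-like cluster held 826 nuclei with a median score of 0.0225, against 1353 and 0.0373 in the main clusters. Added after seeing the data were a doublet score under 0.1, under 0.1% mitochondrial UMIs for E5 over E4, RPE-like nuclei without cluster 4, retinal progenitor-like clusters 1 and 5 one by one, lens fiber-like or lens epithelium-like nuclei alone, shares among nuclei that are not neural retina-like, and shares of retinal sub-classes within the neural retina-like nuclei. The intervals and the rule for named genes were tested on simulated data built from the RET_FGF2 and RET RPE-like counts with 200 changed genes. There, 95.7% of intervals of unchanged genes and 90% to 96% of those of changed genes covered the true value. All of the 20 named genes, 20 of 20, were changed ones. The counts were drawn as Poisson counts, with no variation between nuclei or embryos. The simulation thus checks the computation only, and cannot show how well the intervals suit these data. Python 3.11.15 was used with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, igraph 0.11.9, leidenalg 0.10.2, scikit-image 0.26.0 and matplotlib 3.10.9.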

Results

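Nuclei of chicken eyes, whole ones per the submitters, were compared across 4 pools: E4, E5, E4 collected 6 h after retinectomy (RET), and the same operation with FGF2-soaked beads (RET_FGF2). Each pool joined eyes of 3 embryos, with no replicate pool. The deposited counts held 5414, 10196, 7603 and 8876 nuclei with 37133893, 85900538, 39582272 and 63447099 UMIs. The median nucleus past the filters had 5109, 5053, 4054 and 4974.5 UMIs and 2220, 2216, 1890 and 2204 genes, so RET nuclei were the shallowest. After doublet removal 5076, 9513, 7173 and 8421 nuclei were kept. Values in square brackets are 95% intervals for counting error only. Lists called higher or lower lie outside the central 95% of matched random lists unless their percentile among those is given.

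The first question was what cells each pool holds, since the operation takes out the retina. Neural retina-like nuclei made up 39.7% [38.4, 41.1] of E4 and 61.4% [60.4, 62.4] of E5, against 0.613% [0.446, 0.823] of RET and 1.59% [1.33, 1.88] of RET_FGF2. That is 2017, 5843, 44 and 134 nuclei. The shares that follow are of all nuclei of a pool. RPE-like nuclei, which have the markers of the retinal pigment epithelium (RPE), were 10.6% of E4, 5.21% of E5, 26.3% of RET and 22.4% of RET_FGF2. Lens-like nuclei were 4.35% [3.81, 4.95], 0.894% [0.714, 1.10], 12.3% [11.5, 13.1] and 9.75% [9.12, 10.4]. Ciliary margin or optic stalk-like nuclei were 9.16%, 4.93%, 14.4% and 12.3%, and periocular mesenchyme-like nuclei 16.1%, 13.3%, 18.8% and 19.5%. The mesenchyme share includes clusters 13 and 14, and cluster 14, with a marker of another class among its leading genes, held 94, 164, 303 and 368 nuclei. Ectoderm-like, endothelium-like and cartilage-like nuclei were also a larger share of both operated pools than of E4, at 5.76% and 7.26% against 3.66%, 3.19% and 3.67% against 1.93%, and 5.35% and 5.30% against 3.96%. Skeletal muscle-like nuclei were not, at 1.12% and 1.75% against 1.83%. The cartilage-like class is cluster 10 alone, and no cluster took that name with Leiden at resolution 2 or with predicted doublets kept. At resolution 2 a cluster of 1092 nuclei that shared leading genes with cluster 10, such as CPXM2 and TRABD2B, was named periocular mesenchyme. The split between cartilage and mesenchyme shares thus depends on the clustering. Shares add up to the whole, so the near absence of retina alters the other shares. Among nuclei that are not neural retina-like, RPE-like nuclei were 17.6% of E4, 26.5% of RET and 22.8% of RET_FGF2, and mesenchyme-like nuclei were lower in the operated pools, at 26.7%, 18.9% and 19.8%. By that count ciliary nuclei were 15.2%, 14.5% and 12.5%, ectoderm-like nuclei 6.08%, 5.79% and 7.37%, endothelium-like nuclei 3.20%, 3.21% and 3.73%, and cartilage-like nuclei 6.57%, 5.39% and 5.38%. With Leiden at resolution 2, an unnamed cluster led by TBX5 held 44 RET nuclei, against 448 in unnamed cluster 7 here. Clusters named ciliary then held 330, 55, 123, 34 and 34 E4 nuclei. Their RET nuclei were 224, 761, 257, 228 and 29, and their RET_FGF2 nuclei 661, 79, 304, 202 and 46. Ciliary shares were not computed at that resolution, so their direction from E4 to RET may depend on the clustering.

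Of the neural retina-like nuclei, progenitor-like nuclei were 54.3% in E5 and 78.0% in E4. Photoreceptor precursor-like nuclei were 30.1% and 14.6% of them, ganglion cell-like nuclei 10.7% and 6.05%, and horizontal or amacrine cell-like nuclei 4.98% and 1.34%. The photoreceptor precursor name depends on the clustering. With Leiden at resolution 2, a cluster of 660 E5 and 62 E4 nuclei with NEUROD4 and DLL4 leading was named retinal neurogenic precursor. With predicted doublets kept, a cluster of 582 E5 and 229 E4 nuclei, with leading genes VXN and TFAP2D as in photoreceptor precursor cluster 17, took that name. Among nuclei that are not neural retina-like, lens-like nuclei were 7.22% of E4 and 2.32% of E5. The lens-like share of E5 was thus lower against the rest of the eye, with 85 nuclei in place of 221. Within the lens-like class, fiber-like and epithelium-like nuclei were 479 and 402 in RET and 696 and 125 in RET_FGF2, against 136 and 85 in E4. Of the fiber-like nuclei 334 in RET, 440 in RET_FGF2 and 102 in E4 had a doublet score under 0.1, and of the epithelium-like ones 402, 125 and 81. With Leiden at resolution 2, a cluster with BMPER and ASL1 among its leading genes, 182 RET and 299 RET_FGF2 nuclei and a median doublet score of 0.142 stayed unnamed. With Leiden at resolution 2 the neural retina-like share was 0.321% in RET and 0.629% in RET_FGF2.

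**Figure D1:**
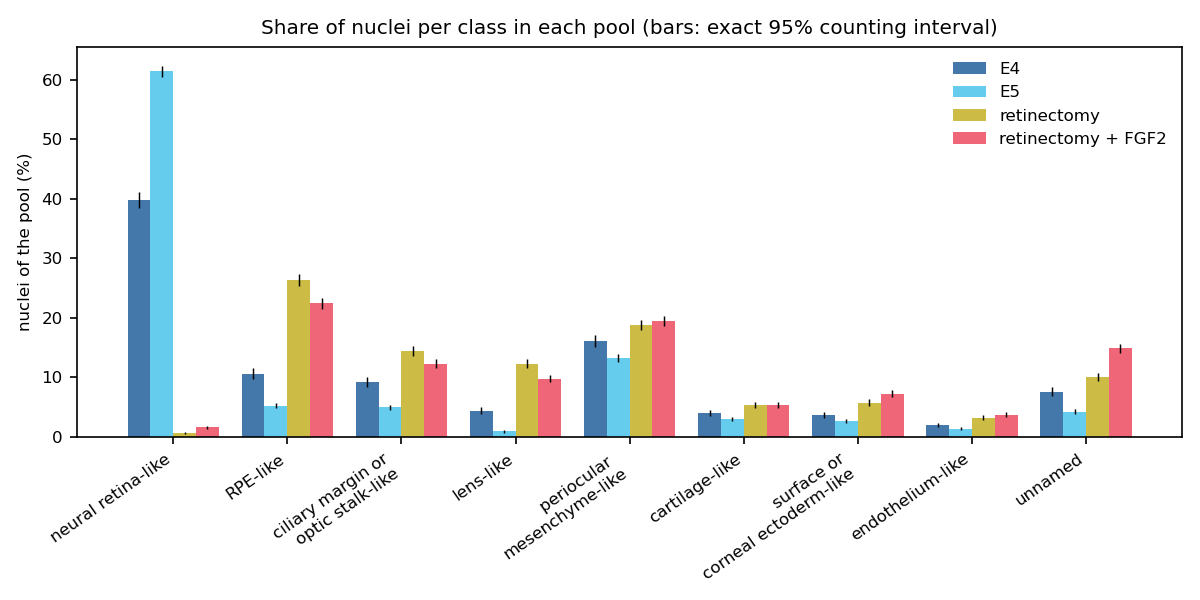
Percent of nuclei (vertical axis) in each class (horizontal axis) for the pools E4, E5, RET and RET_FGF2, shown as bars of different colours. Error bars are exact 95% counting intervals.

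E5 over E4 asks what 1 day of development adds in the lens. In 85 E5 and 221 E4 lens-like nuclei, crystallins were higher at E5 with a median log2 ratio of 1.25 [0.91, 1.53], 6 of 8 members at least 1.5-fold higher and 1 lower. CRYBA4 was higher by 2.45 [1.79, 3.16] on the log2 scale, CRYBA2 by 2.04 [1.49, 2.62], CRYAA by 1.66 [1.30, 2.02] and the small heat shock crystallin CRYAB by 1.34 [1.07, 1.61], all from levels of at most 130.7 CPM at E4. ASL1, which encodes delta-crystallin, the main crystallin of the embryonic bird lens, was already at 5951 CPM at E4 and near that at E5, with a log2 ratio of −0.16 [−0.22, −0.11]. Genes of the fiber membrane and cytoskeleton were almost level, at 0.06 [−0.05, 0.17], with 2 of 15 higher and 1 lower. G2 and M phase genes were higher at 0.71 [0.54, 0.90], 10 of 17 higher and 0 lower, among them BUB1 (1.46) and TOP2A (1.04). Their median was 0.14 for nuclei with a doublet score under 0.1. Among these it was −1.23 [−1.84, −0.68] in fiber-like nuclei and 0.22 [0.06, 0.61] in epithelium-like ones, with 5 of 15 higher and 0 lower in the latter. BUB1 was at 2.20 with predicted doublets kept. CRYAA was higher by 0.78 as a mean over nuclei. It went from 35.40 to 331.4 CPM in epithelium-like nuclei, and from 76.62 [62.79, 92.58] to 114.3 [82.72, 154.0] in fiber-like ones. In fiber-like nuclei with a doublet score under 0.1 it went from 111.3 to 195.8.

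Among the genes named by rule in the E5 lens-like nuclei were PIEZO2, a mechanosensitive channel, higher by 2.64 [2.07, 3.24], the carboxypeptidase CPA6 (2.59), CLVS1 (2.46), the cadherin PCDH15 (2.77), the serotonin receptor HTR4 (2.95) and ADAMTS3, a procollagen peptidase (1.87). HSF4, a heat shock factor linked to cataract, went from 2.100 to 24.36 CPM, a log2 ratio of 3.41 [1.90, 5.58]. Lens transcription factors as a list were at 0.26, with 4 of 13 higher and 1 lower. MEIS2 was lower, at −0.81 [−0.96, −0.66], and BMP targets were lower with a median of −0.52 [−0.84, −0.24], 3 of 6 lower and 0 higher, ID3 among them at −1.36. Other lower genes were ELMO1 (−1.45) and the potassium channel gene KCNQ3 (−2.91). With predicted doublets kept, where nuclei were also clustered and named anew, several calls moved: HTR4 and PCDH15 to 3.91 each, RUNX2 from 2.44 to 0.24, NTN1 from −3.60 to −0.78, ALDH1A3 from −3.26 to −0.82, STAC from −3.15 to −1.11, SYT10 from −2.14 to −0.85, ADAMTS20 from −2.03 to −0.81, MECOM from −1.95 to −0.57, BMP7 from −0.95 to −0.19 and KCNQ3 to −1.29. OPCML, at 4.04, was at 1.37 for nuclei with a doublet score under 0.1. As means over nuclei CPA6 stood at 3.26, CLVS1 at 1.82, ELMO1 at −0.76 and HSF4 at 5.34. NTN1, ALDH1A3 and KCNQ3 are among the 10 leading genes of a ciliary cluster at Leiden resolution 2, with 123 E4 and 53 E5 nuclei. Whether RNA of ciliary nuclei brought part of the counts of these genes was not tested.

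The ages differ in their mix of fiber-like and epithelium-like nuclei, 42 and 43 at E5 against 136 and 85 at E4, so lists are also given by sub-class. Genes linked to inherited cataract stood at 0.12 with 5 of 20 higher and 1 lower, but were higher in fiber-like nuclei at 0.40 [0.26, 0.50], 7 of 20 higher and 2 lower, and at 0.24 [−0.08, 0.48] in epithelium-like nuclei. Heterochronic genes stood at −0.15, but were lower in fiber-like nuclei at −0.42 [−0.63, −0.24] and near level in epithelium-like ones. Notch pathway genes stood at 0.25, but were higher in fiber-like nuclei at 0.65 [0.24, 0.97], 5 of 9 higher and 1 lower, though at −0.32 [−0.83, 0.06] for those with a doublet score under 0.1, and stood at −0.02 [−0.42, 0.41] in epithelium-like nuclei. Retinal neurogenesis genes were higher in epithelium-like nuclei, at 2.04 [1.27, 3.11] with 4 members measured, and the neural retina-like share was 39.7% of E4 and 61.4% of E5. For epithelium-like nuclei with a doublet score under 0.1 fewer than the 3 members needed were measured, so that call could not be repeated. RORB in fiber-like nuclei was at 880.7 CPM in E4 and 1499 in E5, but at 723.5 and 578.0 for those with a doublet score under 0.1. In epithelium-like nuclei it was at 800.5 and 1411, but at 600.3 and 714.3 with such a score. Fiber membrane and cytoskeleton genes were higher in epithelium-like nuclei, at 0.53 [0.27, 0.75]. BMP targets, lower in all lens-like nuclei, were at −0.48 in fiber-like and −0.17 [−0.84, 0.32] in epithelium-like nuclei. Organelle clearance and autophagy genes and YAP and TEAD targets were near level in all lens-like nuclei, both at −0.06. Hypoxia and glycolysis genes stood at 0.26, Wnt targets at −0.17, collagens at −0.02 and FGF and ERK feedback targets at 0.02. With a doublet score under 0.1 collagens stood at −0.47 [−0.71, 0.05] in lens-like nuclei. They were then at −0.81 [−1.15, −0.31] in fiber-like nuclei, 6 of 11 lower and 0 higher, and at −0.04 [−0.29, 0.28] in epithelium-like ones.

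Lens fiber-like and epithelium-like nuclei were compared within E4 (136 and 85 nuclei) and within E5 (42 and 43). Since fiber genes name these clusters, the fiber membrane list only checks the naming, at 1.35 [1.04, 2.04] in E4 and 2.08 [1.48, 2.62] in E5. Outside the markers, a gene with a high ratio in fiber-like nuclei of both ages was BMPER, which encodes a secreted BMP-binding protein, at 1690 CPM against 11.8 in E4 and 4950 against 3.56 in E5, log2 ratios of 7.05 [6.04, 8.61] and 9.86 [7.96, 15.74]. BMPER in fiber-like nuclei was higher at E5 by 1.55 [1.46, 1.64]. For nuclei with a doublet score under 0.1 it was at 2780 CPM in E4 and 8326 in E5. NRCAM, a neural adhesion molecule, was higher in fiber-like nuclei by 6.63 [5.88, 7.64] in E4 and 4.75 [4.22, 5.38] in E5, the phosphatase subunit gene PPP2R2C by 7.01 [5.68, 9.51] and 7.32 [5.41, 13.21], and GYPC, a membrane skeleton glycoprotein, by 6.12 and 6.56. With predicted doublets kept BMPER was at 8.48 and 11.70, NRCAM at 9.89 and 6.83, TGFB2 at −3.84 and −3.47, HTRA3 in E4 at −6.53 and GYPC in E5 at 10.01, and as a mean over nuclei PPP2R2C was at 8.15 and 5.91. Higher in the epithelium were TGFB2, with log2 ratios of −3.10 [−3.18, −3.01] and −2.49 [−2.66, −2.33], and in E4 THSD7B (−2.97) and the serine protease gene HTRA3 (−3.01). G2 and M phase genes were higher in the epithelium, with −0.85 in E4 (12 of 16 lower in fibers, 0 higher) and −1.04 in E5 (12 of 15 and 0). BMPER lies on chromosome 2 at 47436151 to 47583594 (ENSGALG00010019124) and CRYBA4 on chromosome 15 at 7189310 to 7190515 (ENSGALG00010023618).

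E5 over E4 in the retina rests on 5843 and 2017 neural retina-like nuclei. Retinal neurogenesis genes were higher at E5, with a median of 1.27 [1.17, 1.58], 13 of 15 higher and 0 lower. By sub-class the median was 1.39 [1.01, 1.83] in progenitor-like and 1.05 [0.49, 1.30] in ganglion cell-like nuclei, but near 0, [−0.24, 0.23], in photoreceptor precursor-like nuclei, with 5 of 13 higher and 2 lower. The name of that last class depends on the clustering, as given above. Progenitor-like nuclei lie in cluster 1, with 1897 E5 and 1374 E4 nuclei, and in cluster 5, with 1273 and 200 and a median of 1.62% mitochondrial UMIs. Within cluster 1 the median was 0.47 [0.11, 1.06] and within cluster 5 it was 0.76 [0.36, 1.41]. The mix of retinal types also differed between the ages, as given above. The proneural factors NEUROD1, NEUROD4 and ATOH7 were higher by 2.68 [2.48, 2.90], 2.41 [2.25, 2.58] and 1.27 [1.18, 1.36], and the neurofilament gene NEFM by 1.80 [1.71, 1.90]. Among the genes named by rule were TUBB3, neuronal tubulin, higher by 3.19 [3.04, 3.34], TUBB2B (2.98), TMSB4X (3.10), RBP4 (3.21), the photoreceptor-linked nuclear receptor gene RXRG (2.78), KLHL4 (2.87), GDF3 (2.85) and EGFLAM, 3.42 [3.08, 3.80], which encodes pikachurin of the photoreceptor synapse. NEUROD1, NEUROD4, RBP4 and RXRG are among the 10 leading genes of photoreceptor precursor cluster 11, which held 1211 E5 and 74 E4 nuclei. Notch pathway genes were higher at 0.68, 6 of 12 higher and 0 lower, with NOTCH1 at 1.43 and HES1 at 1.78. Cell cycle exit genes stood at 0.83, and eye field and progenitor regulators at 0.48 with 3 of 12 higher and 2 lower. S phase genes were higher at 0.94 with PCNA at 1.67, and G2 and M phase genes at 0.47 [0.39, 0.54] with TOP2A at 1.38.

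Lower in the E5 retina were SEMA3E, a guidance cue, at −2.86 [−3.00, −2.73], KIAA1217 (−2.58), SYT10 (−2.46), FLT1, a VEGF receptor (−2.54), PRTG, a receptor of early neural tissue (−2.49), DPF3 (−2.11) and STAC (−2.05). SEMA3E was at −2.06 with predicted doublets kept and STAC at −1.29 as a mean over nuclei. SEMA3E is among the 10 leading genes of ciliary cluster 3, and SYT10 among those of ciliary clusters at Leiden resolution 2. STAC is among those of unnamed cluster 7, which held 230 E4 and 73 E5 nuclei. Ciliary nuclei were 9.16% of E4 and 4.93% of E5. Whether RNA of such nuclei brought part of these 3 genes' counts was not tested. Heterochronic genes stood at −0.49, percentile 6.70, with HMGA2 at −1.38 [−1.40, −1.35] and LIN28B at −0.73 [−0.78, −0.67], and Wnt targets at −0.41 with 3 of 8 lower and 0 higher. Hypoxia and glycolysis genes were higher at 0.55. Immediate early genes stood at 0.77, percentile 96.3, and p53 and damage response genes at 0.29, close to the 0.24 of random lists. TUBB3 lies on chromosome 11 at 18489877 to 18492525 (ENSGALG00010008107), EGFLAM on Z at 12471454 to 12544743 (ENSGALG00010012913), and SEMA3E on 1 at 9710324 to 9843704 (ENSGALG00010006251). The median E5 retinal nucleus held 0.400% mitochondrial UMIs against 0.0208% at E4. In nuclei under 0.1% mitochondrial UMIs the S phase median was 0.30, the G2 and M phase median 0.08 [0.02, 0.14] and the neurogenesis median 0.76 [0.55, 0.83].

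**Figure D2:**
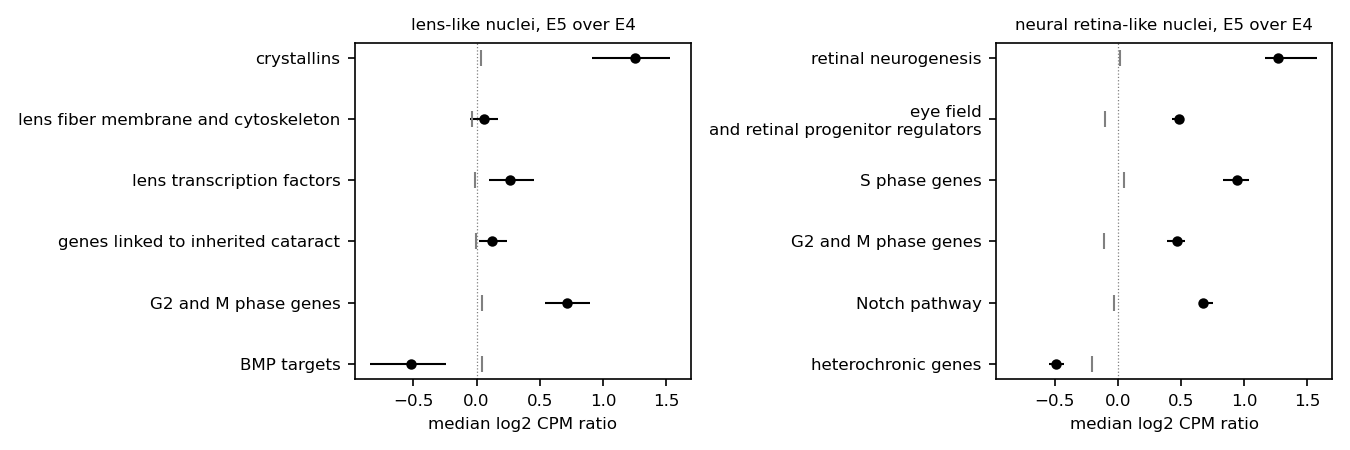
Median log2 CPM ratio of E5 over E4 (horizontal axis) for gene lists (vertical axis) in lens-like nuclei, left, and neural retina-like nuclei, right. Dots are medians, bars 95% counting intervals, and grey ticks the median of matched random lists.

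RET over E4 asks what differs in the remaining eye 6 h after the retina is taken out. The E4 pool was unoperated and is not stated to have had a sham operation or the extra 6 h. Heat shock and stress chaperone genes were lower in RET than in E4, with medians of −0.97 [−1.12, −0.82] in RPE-like, −0.93 in ciliary, −0.46 in lens-like, −0.65 in mesenchyme cluster 2, −0.63 in ectoderm-like and −0.62 in endothelium-like nuclei, but 0.10 in the lens epithelium-like part. The lens-like median was −0.11 [−0.42, 0.10] for nuclei with a doublet score under 0.1. The list was also lower in E5 over E4, without an operation, at −0.49 in RPE-like and −0.80 [−1.14, −0.53] in lens fiber-like nuclei, the latter at −0.31 [−1.01, 0.07] with a score under 0.1. Genes on chromosome Z were lower in RET in all 6 classes measured, by −0.24 to −0.40 against the autosomes, and in mesenchyme UBAP2L2 and HNRNPKL, both on chromosome W, were higher by 1.56 [1.38, 1.75] and 1.41 [1.13, 1.72]. Sex was not given for the embryos in the sources used here.

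In RPE-like nuclei (1888 RET, 539 E4) immediate early genes were higher in RET, with a median of 1.41 [0.95, 1.92], 9 of 11 higher and 0 lower. FOSL2 was higher by 2.72 [1.92, 3.81], KLF6 by 1.77 [1.18, 2.49], and EGR1 by 4.16 [2.22, 10.06], from 0.390 to 10.41 CPM. Wound matrix and adhesion genes were higher at 0.87 [0.50, 1.18], 9 of 14 higher and 2 lower, with the matrix genes TNC at 1.29 and TGFBI at 1.71. Inflammation genes were higher at 0.83, 6 of 7 higher, STAT3 among them at 1.35 [0.91, 1.85]. Pigment genes were lower at −0.48 [−0.54, −0.42], 4 of 13 lower and 1 higher, and MITF, the master regulator of pigment cells, at −1.11 [−1.20, −1.02]. G2 and M phase genes were lower at −1.04, 16 of 17 lower and 0 higher, with BUB1 at −1.65, and S phase genes at −0.44. Cluster 4, with RUNX1 among its leading genes, held 253 of the RET and 0 of the E4 RPE-like nuclei. Without it the immediate early median was 0.68, the wound median 0.14, FOSL2 was at 1.64 and KLF6 at 0.42, while pigment genes were at −0.34 and G2 and M phase genes at −1.28.

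Among the genes named by rule in RET RPE-like nuclei were RUNX1, a transcription factor of blood formation, at 144.7 CPM against 3.51 in E4, a log2 ratio of 5.29 [4.44, 6.50], the receptor phosphatase gene PTPRO, 3.61 [3.19, 4.09], both members of a ligand and receptor pair, HGF (3.51) and MET (3.79), the integrin ITGA4 (3.54), STARD13 (3.16), PIEZO2 (2.77) and the neurotrophin receptor NTRK3 (2.95). Lower were SERPINE3, a serpin, at −4.47 [−5.04, −3.98], FAM124A (−3.91), the Wnt inhibitor gene DKK2 (−2.47), the protease gene ADAMTS18 (−1.51), INPP4B (−1.47), the retinoid-metabolizing CYP1B1 (−1.63), NAV3 (−1.54) and the chaperones DNAJA1 (−1.66) and HSP90B1 (−1.57). Wnt targets stood at 0.44, collagens at 0.36, heterochronic genes at −0.33, and p53 and damage response genes at 0.33 with 3 of 7 higher and 1 lower. FGF and ERK feedback targets had a median of 0.73 [0.27, 1.18], but it was −0.10 in sublibraries 1 to 3, 0.07 in sublibraries 4 to 7 and 0.0156 without cluster 4. Measured members, with at least 20 UMIs, were chosen anew in each setting, so these medians can rest on fewer members. Without that cluster RUNX1 was at 0.36, MET at 0.61, PTPRO at 0.88, STARD13 at 1.66, ITGA4 at 2.11 and HGF at 2.96. As a mean over nuclei SERPINE3 was at −5.34. RUNX1 lies on chromosome 1 at 106105351 to 106258778 (ENSGALG00010012917), PTPRO on 1 at 62840931 to 62990143 (ENSGALG00010012702), HGF on 1 at 10859559 to 10922316 (ENSGALG00010010439) and SERPINE3 on 1 at 169957651 to 169977844 (ENSGALG00010002897).

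In ciliary margin or optic stalk-like nuclei (1036 RET, 465 E4) FGF and ERK feedback targets were lower after the operation, at −1.29 [−1.50, −1.04], 10 of 11 lower and 0 higher. SPRY2 was at −2.67 [−3.31, −2.10] and ETV4 at −2.79 [−3.93, −1.88], or −3.45 as a mean over nuclei. Pigment genes were higher at 1.23 [1.06, 1.53], 13 of 13, with OCA2 at 2.43 [2.20, 2.67] and MITF at 1.23 [1.05, 1.41]. Wnt targets were higher at 0.96, 5 of 7, with AXIN2 at 1.48, and collagens at 0.59. G2 and M phase genes were lower at −1.20, 16 of 17, and S phase genes at −0.83. Higher genes were ENOX1 (3.18), the basement membrane gene FREM1 (3.18), the calcium channel subunit CACNA2D4 (3.26), ASTN2 (2.81), PDZRN3 (2.54), the epithelial factor BNC1 (2.79), the ion transporter SLC12A2 (2.46) and FGF7 (2.59). Lower were PRSS56, a serine protease, at −5.79 [−7.56, −4.68], FOXN4, a factor of retinal progenitors (−3.80), TRIM71 (−3.03), COL25A1 (−2.81) and the Notch ligand gene JAG2 (−2.62). PRSS56 and COL25A1 are among the 10 leading genes of retinal progenitor cluster 1, and neural retina-like nuclei were 39.7% of E4 and 0.613% of RET. The class joins clusters of unlike origin: cluster 16 held 785 of the RET and 35 of the E4 nuclei, and cluster 3 held 222 and 396.

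In lens-like nuclei (881 RET, 221 E4) crystallins were higher in RET at 1.14 [0.83, 1.59], 8 of 11 higher and 0 lower, with CRYAB at 1.49 [1.30, 1.68] and CRYBA2 at 1.89 [1.47, 2.36]. The median was 0.61 as a mean over nuclei. FGF and ERK feedback targets were lower at −0.53 [−0.78, −0.30], 4 of 10 lower and 1 higher, with DUSP6 at −2.04 and SPRY2 at −1.75. BMPER was lower by −4.12 [−4.27, −3.98] in lens-like nuclei. In fiber-like nuclei it was at 101.3 CPM against 1690, and at 32.52 against 2780 for nuclei with a doublet score under 0.1, for which the lens-like log2 ratio was −6.52. JAG1 (−1.41), Notch pathway genes as a list (−0.48), RORB (−2.98), THSD7B (−2.11) and ADAMTS18 (−2.19) were also lower. CPA6 (3.07), the polarity gene PRICKLE1 (2.71) and FREM1 (2.32) were higher, with PRICKLE1 at 3.65 for nuclei with a doublet score under 0.1. Genes linked to inherited cataract stood at 0.30, 9 of 24 higher and 1 lower, wound genes at 0.40, G2 and M phase genes at −0.49 and pigment genes at 0.99, 9 of 13 higher. RPE-like nuclei were 26.3% of RET and 10.6% of E4. TYR was at 211.2 CPM in RET fiber-like nuclei, 100.3 at a doublet score under 0.1, and 5.68 in epithelium-like nuclei. PRSS56 (−6.20), COL25A1 (−2.64) and ALDH1A1 (−3.85) were lower too. PRSS56 and COL25A1 lead a retinal progenitor cluster, as given above, and neural retina-like nuclei were 39.7% of E4 and 0.613% of RET. RORB in E4 was at 880.7 CPM in fiber-like and 800.5 in epithelium-like nuclei, but at 723.5 and 600.3 with a doublet score under 0.1. Its lens-like log2 ratio was −3.29 at that score. Whether RNA of retinal nuclei brought part of the RORB counts was not tested. With predicted doublets kept COL25A1 was at −4.89, ALDH1A1 at −3.18 and SPRY2 at −2.47, and PRSS56 was at −5.36 as a mean over nuclei.

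In mesenchyme cluster 2 (1013 RET, 605 E4) differences were smaller. Collagens were higher at 0.55 [0.41, 0.68], 5 of 13 higher and 0 lower, with COL6A1 at 1.87 and COL1A1 at 0.74, and IYD (1.78) and BMP5 (1.37) were higher. BMP targets stood at 0.40 and p53 and damage response genes at 0.51, 3 of 6 higher. The mesenchymal factor TBX15 (−2.73), GDF10 (−2.53) and FGF and ERK feedback targets (−0.35, 3 of 10 lower) were lower.

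RET_FGF2 over RET asks what FGF2 beads add to the operation. The conditions as described name no beads without FGF2. FGF2 thus cannot be told apart from the beads or their heparin coat, and "with FGF2" below refers to the RET_FGF2 pool. FGF and ERK feedback targets were higher in each class compared: 1.72 [1.45, 1.97] in RPE-like, 2.65 [2.16, 3.16] in ciliary, 2.09 [1.66, 2.57] in lens-like, 1.43 [1.12, 1.77] in mesenchyme, 1.19 [0.87, 1.71] in ectoderm-like and 0.50 [0.31, 0.72] in endothelium-like nuclei. Of 12 members in each, 11, 12, 10, 11, 10 and 5 were at least 1.5-fold higher and 0 lower. G2 and M phase genes were higher in the first 5, at 0.91, 0.96, 0.77, 0.50 and 0.59, and stood at 0.22, percentile 94.3, in endothelium-like nuclei. Z-linked genes were higher by 0.30 to 0.43 against the autosomes, the reverse of RET over E4, and UBAP2L2 in mesenchyme was lower at −1.86.

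**Figure D3:**
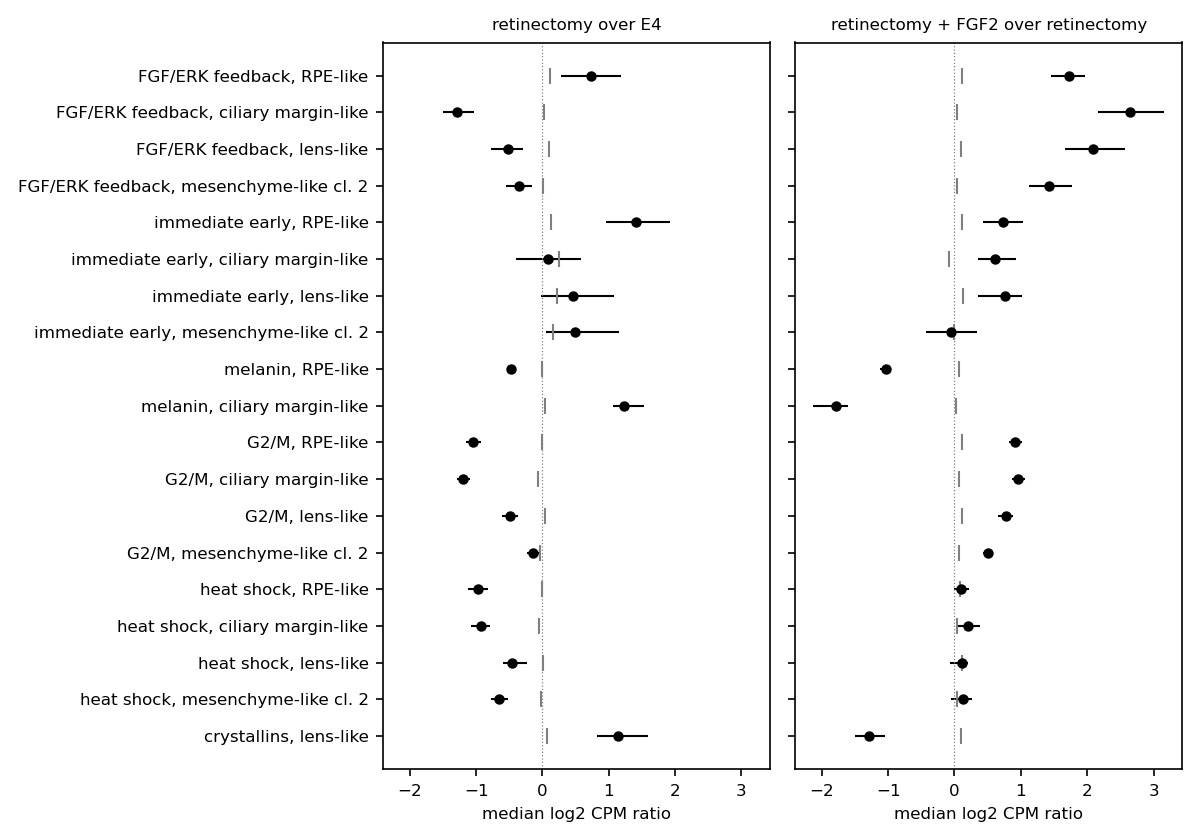
Median log2 CPM ratio (horizontal axis) for gene lists and classes (vertical axis), RET over E4 on the left and RET_FGF2 over RET on the right. Dots are medians, bars 95% counting intervals, and grey ticks the median of matched random lists.

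In RPE-like nuclei (1888 in each pool) pigment genes were lower with FGF2, at −1.03 [−1.12, −0.97], 12 of 13 lower and 0 higher. OCA2 was lower by −1.30 [−1.36, −1.24] and TYR, the rate-limiting enzyme of melanin synthesis, by −1.03 [−1.08, −0.99], while MITF was at −0.35 [−0.43, −0.27]. The feedback genes SPRY4, DUSP6, SPRY2 and ETV4 were higher by 3.51 [3.00, 4.12], 2.70 [2.37, 3.07], 2.53 [2.10, 3.00] and 2.34 [2.06, 2.65]. S phase and G2 and M phase genes were each higher at 0.91, with 14 and 15 of 17 higher, UHRF1 at 1.32 and TOP2A at 1.20. The eye field gene SIX6 was higher by 2.37 [1.94, 2.84], the Notch ligand DLL1 by 1.63, Notch pathway genes by 0.63, or 0.09 [−0.11, 0.82] for nuclei with a doublet score under 0.1, immediate early genes by 0.73 and wound genes by 0.51. Lens transcription factors stood at 0.54, 5 of 10 higher and 0 lower.

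Among the genes named by rule in RPE-like nuclei were NRG1, an ERBB ligand, higher by 3.84 [3.55, 4.16], HMP19 (3.55), ALDH1A1, which makes retinoic acid (3.57), CYP26B1, which breaks it down (3.51), PTPRO at 1871 against 211.2 CPM (3.15), HGF (3.18), GALNT7 (3.32), the zinc finger factor TSHZ2 (3.17), ASIC2 (3.32) and the T-box factor TBX20 (3.26). PTPRO and HGF were thus higher both in RET over E4 and with FGF2. Lower were the heparan sulfate enzymes HS3ST3B1, −3.69 [−3.92, −3.46], and HS3ST5 (−2.44), PDC, phosducin (−3.05), LRFN2 (−2.63), FSTL5 (−2.60), BNC1 (−2.37), the potassium channel KCNG2 (−2.21), the hedgehog-binding HHIP (−2.05), PLCL1, at 278.2 against 1112 CPM, and NTRK3 (−2.21), which was higher in RET than in E4. With predicted doublets kept ALDH1A1 was at 1.47, HMP19 at 4.89, TSHZ2 at 2.26 and DLL1 at 0.71. For nuclei with a doublet score under 0.1 ALDH1A1 was at 2.74 and TSHZ2 at 2.77, and both are among the 10 leading genes of unnamed cluster 7. NRG1 lies on chromosome Z at 54642186 to 55109784 (ENSGALG00010013914). Cluster 4 held 1432 of the RET_FGF2 and 253 of the RET nuclei. Without it the pigment median was −0.01, OCA2 was at −0.24 and TYR at −0.07, the FGF and ERK median was 0.50 and the immediate early median −0.45, the wound median −0.04, the Notch median 0.16 and the lens transcription factor median 0.11, while S phase genes were at 0.70 and G2 and M phase genes at 0.98. NRG1, TBX20, DLL1 and ALDH1A1 were then lower, at −0.58, −0.82, −0.87 and −0.30, and MITF was at 0.28. Also without it SPRY4 was at 1.46, SPRY2 at 1.17, ETV4 at 0.82, DUSP6 at 0.36, SIX6 at 0.48, PTPRO at 1.58, GALNT7 at 1.40, ASIC2 at 1.36, CYP26B1 at 0.62, HMP19 at 0.32 and TSHZ2 at 0.24. On the lower side PDC was then at −2.53, HS3ST3B1 at −2.18, KCNG2 at −1.46, BNC1 at −1.39, LRFN2 at −1.26, FSTL5 at −1.17, HS3ST5 at −0.88, NTRK3 at −0.81 and HHIP at −0.48.

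In ciliary margin or optic stalk-like nuclei (1034 RET_FGF2, 1036 RET) SPRY2 was higher by 4.76 [4.26, 5.36], DUSP6 by 3.44 [3.02, 3.91], the cytokine receptor CNTFR by 4.54 [4.21, 4.91], HGF by 3.56 [3.44, 3.68], FOXN4 by 3.72, PLXND1 by 3.63, the paired box factor PAX5 by 3.52, SHANK2 by 3.27, TRIM71 by 2.79, JAG2 by 2.54 and DLL1 by 1.25. Pigment genes were lower at −1.79 [−2.14, −1.61], 13 of 13, with OCA2 at −2.24. Also lower were SLC38A8 (−3.85), BNC1 (−3.70), PDZRN3 (−3.16), FMN2 (−3.04), SLC12A2 (−2.87) and HHIP (−2.72), the YAP and TEAD targets at −0.87, 4 of 6 lower, and Wnt targets at −0.52. FOXN4, TRIM71, JAG2 and SPRY2 were lower, and BNC1, PDZRN3, SLC12A2 and OCA2 higher, in RET over E4, and both ratios share the RET pool. Cluster 16 held 38 and cluster 3 held 949 of the RET_FGF2 nuclei. The FGF and ERK median was 3.28 in sublibraries 1 to 3, the pigment median was −1.21 with Leiden at resolution 2, HHIP was at −1.47 with predicted doublets kept, and PAX5 at 4.39 as a mean over nuclei. SPRY2 lies on chromosome 1 at 152630538 to 152636591 (ENSGALG00010000711).

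In lens-like nuclei (821 RET_FGF2, 881 RET) BMPER was higher with FGF2 by 4.65 [4.51, 4.79], and 7.41 for nuclei with a doublet score under 0.1. In fiber-like nuclei BMPER was at 1905 CPM, near the E4 level of 1690, but for nuclei with a doublet score under 0.1 it was at 3963 against 2780. DUSP6 was higher by 4.63 [3.97, 5.49], SPRY1 by 3.89, ETV4 by 3.10, PTPRO by 4.11, HGF by 3.66, RUNX1 by 3.45, the interleukin 1 receptor IL1R1 by 4.55, ALDH1A1 by 3.39, DPP6 by 2.93, RASGEF1A by 2.90 and TSHZ2 by 2.89. Crystallins were lower at −1.28 [−1.51, −1.05], 10 of 12 lower and 0 higher, with CRYBA2 at −1.89 [−2.11, −1.68], CRYAB at −1.46 [−1.56, −1.36], CRYAA at −1.42 and ASL1 at −0.69. Genes linked to inherited cataract were lower at −0.70, 13 of 24 lower and 1 higher, lens transcription factors at −0.48 and fiber membrane genes at −0.40. Also lower were FAM135B (−3.61), KCNIP2 (−2.17), CPA6 (−2.08), CNTN5 (−2.05), VIT (−2.02), the retinoid transporter ABCA4 (−1.97) and SYN3 (−1.96). Inflammation genes were higher at 1.22, 6 of 8, collagens at 0.53, wound genes at 0.60 and S phase genes at 0.59.

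Doublets and the mix of lens-like nuclei weigh on these lens values. The crystallin median was −0.61 with predicted doublets kept and classes named anew, −0.65 for nuclei with a doublet score under 0.1, −0.67 with Leiden at resolution 2 and −0.69 as a mean over nuclei. Fiber-like nuclei alone gave −1.50 and epithelium-like nuclei −0.40, and ASL1 was at −0.12 for nuclei with a doublet score under 0.1. At that same score CRYAB was at −0.79, CRYBA2 at −1.11, CRYAA at −0.55, SYN3 at −1.36, ABCA4 at −1.34, DPP6 at 3.79, RASGEF1A at 3.53 and IL1R1 at 5.75. ALDH1A1 was then at 1.56 [0.92, 2.28] and TSHZ2 at 2.34. ALDH1A1 and TSHZ2 are among the 10 leading genes of unnamed cluster 7, which held 448 RET and 683 RET_FGF2 nuclei. With predicted doublets kept ALDH1A1 was at 0.49, TSHZ2 at 1.83, FAM135B at −2.58, KCNIP2 at −1.47 and CNTN5 at −1.46. For nuclei with a score under 0.1 wound genes were at −0.02, S phase genes at −0.16 [−0.39, 0.04], G2 and M phase genes at 0.12, fiber membrane genes at −0.08, lens transcription factors at −0.16 and cataract genes at −0.32. Those nuclei were 334 fiber-like and 402 epithelium-like in RET, but 440 and 125 in RET_FGF2. The pooled medians carry that change of mix, so they do not show that the differences are absent within a sub-class. Inflammation genes were at 0.13 with doublets kept, 0.37 with a score under 0.1, 0.06 with Leiden at resolution 2 and −0.26 in epithelium-like nuclei. FGF and ERK feedback targets were at 1.84 in fiber-like and 0.72 in epithelium-like nuclei. RUNX1 in fiber-like nuclei was at 23.77 CPM in RET and 216.0 in RET_FGF2. In epithelium-like nuclei it was at 6.71 [3.57, 11.47] and 10.69 [4.30, 22.04], with 13 and 7 UMIs. PTPRO was at 42.75 and 703.8 CPM in fiber-like and 28.90 and 125.3 in epithelium-like nuclei.

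In mesenchyme cluster 2 (1195 RET_FGF2, 1013 RET) the kinase gene RPS6KA2 was higher with FGF2 by 4.41 [3.87, 5.08], RUNX1 by 3.45 [3.13, 3.81], PTPRO by 2.74 [2.52, 2.97], SPRY2 by 2.15 and TRABD2B by 1.91. The glutamate receptor GRM3 (−4.13), the protease PAPPA (−1.62) and BMPER (−1.75) were lower, so BMPER differs in opposite directions in mesenchyme and lens. In ectoderm-like nuclei (611 and 413) RUNX1 was higher by 4.59 [4.04, 5.27], or 3.68 [3.04, 4.49] for nuclei with a doublet score under 0.1 and 3.49 as a mean over nuclei, HGF by 3.66 [3.30, 4.07] and wound genes by 0.40.

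RET_FGF2 over E4 sums both steps. In RPE-like nuclei RUNX1 was at 795.3 against 3.51 CPM, higher by 7.75 [6.90, 8.95], LRRTM3 by 7.39 [5.86, 10.76], PTPRO by 6.75, HGF by 6.69 and ITGA4 by 6.33. Without cluster 4, which held no E4 nuclei, these were 2.05, 1.37, 2.46, 4.46 and 3.08. FGF and ERK feedback targets were higher at 2.59, 10 of 12, immediate early genes at 2.26, 10 of 11 with 1 lower, and inflammation genes at 1.88, or 1.82 with the floor for 2 members at 0 counts. Pigment genes were lower at −1.47, 12 of 13, and G2 and M phase genes near level at −0.16. Without cluster 4 these medians were 0.61, 0.57 with 4 members measured, 1.03, −0.35 and −0.31. In ciliary nuclei FGF and ERK feedback targets stood at 0.98, pigment genes at −0.46 and G2 and M phase genes at −0.08. In lens-like nuclei FGF and ERK feedback targets were higher at 1.21, 9 of 12, immediate early genes at 1.54, collagens at 0.91 and inflammation genes at 1.48, or 1.17 with the floor for 3 members at 0 counts, while crystallins were at −0.27. For nuclei with a doublet score under 0.1 these medians were 1.09, 0.55, 0.41 and 0.71, and crystallins were higher instead, at 0.32 [0.13, 0.61]. Heat shock genes were lower than in E4 here too, at −0.59, −0.82 and −0.31, the last at −0.17 [−0.67, 0.01] with a score under 0.1.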

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

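All tests named below were chosen only after the result they test was seen. The differences in the next paragraph were singled out because list medians pointed in opposite directions between classes or pools, and they were not tested.

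Pigment genes differed between classes in RET over E4: the median was −0.48 in RPE-like nuclei, but 1.23 in ciliary margin or optic stalk-like, 0.99 in lens-like and 0.93 in lens fiber-like nuclei. They were also higher in ectoderm-like nuclei, as given below, so the rise is not particular to ciliary and lens nuclei. RPE-like nuclei were 10.6% of E4 and 26.3% of RET. Notch pathway genes in RET_FGF2 over RET were higher in ciliary (0.75) and lens fiber-like nuclei (0.45) and lower in endothelium-like nuclei (−0.35). Retinal neurogenesis genes in RET_FGF2 over E4 stood at 1.05 in ciliary nuclei, with 3 members measured, and at −0.33 in endothelium-like nuclei, with 4. For nuclei with a doublet score under 0.1 the endothelium-like values were −0.0247 for Notch and 0.0112 for neurogenesis. A further 26658 nuclei lie in wells that the labels give to no condition, and they were not analysed here.

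RUNX1, PTPRO and HGF, which lead in RPE-like or ciliary nuclei of the FGF2 pool, were also counted in its other classes, so free RNA or doublets from RPE-like nuclei could be their source. The test took nuclei with a doublet score under 0.1 and divided each gene's CPM by the most that RPE-like RNA can bring, judged from pigment genes. Only pigment genes with many UMIs in the source were used: TYR, OCA2 and PMEL, and DCT for all RPE-like nuclei but not for cluster 4. The lowest ratio over the 3 genes was 1.20 [1.06, 1.34] in mesenchyme cluster 2 and 1.25 [1.11, 1.39] in lens fiber-like nuclei. That is more than RPE-like RNA brings by the pigment genes used. Pigment genes scarcer in cluster 4 could allow a larger share, so RPE-like RNA as the source is not excluded. In ectoderm-like nuclei it was 0.783 [0.703, 0.870], set by RUNX1 (PTPRO 2.59, HGF 1.03), and in endothelium-like nuclei 0.467 [0.359, 0.598], also set by RUNX1 (PTPRO 0.622, HGF 2.19), so there expression and carried-over RNA cannot be told apart. Ciliary nuclei as a source of HGF were not tested, so expression of all 3 genes in mesenchyme and lens fibers is a hypothesis.

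UBAP2L2 and HNRNPKL, on chromosome W, were higher in the RET pool, for which a higher share of female embryos is a candidate explanation. A first test on 6 W-linked genes gave no decision and was replaced by a test on Z-linked genes, which females carry in 1 copy: in mesenchyme the W-linked median was 0.64 in RET over E4, with single genes from −1.01 to 1.62, and 0.12 in RET_FGF2 over E4, with −0.30 to 0.31. Z minus autosomal medians in RET over E4 were −0.24 [−0.29, −0.20] in the class nearest 0, ciliary nuclei, so lower Z-linked levels go along with a higher female share. A response to the operation itself predicts the same in RET_FGF2 over E4, but there the lowest value was −0.0226 [−0.0605, 0.0346], in endothelium-like nuclei. The sex of the embryos was not given, and any difference that goes with sex stays open in both comparisons with RET. Z-linked genes were not examined in E5 over E4, so sex stays open there too.

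In E5 neural retina-like nuclei ribosomal protein genes were higher by 1.59 together with neurogenesis and cell cycle genes, and more cytoplasmic RNA around the E5 nuclei could be the source. In nuclei under 0.1% mitochondrial UMIs, 42.1% of E5 (2459) and 71.0% of E4 (1433), the ribosomal median was 0.14 [0.07, 0.21] and the G2 and M phase median 0.0839 [0.0240, 0.142], as cytoplasmic RNA predicts. The neurogenesis median was 0.76 [0.55, 0.83], against 1.27 in all nuclei, and the S phase median 0.30 [0.18, 0.44], against 0.94, so for these cytoplasmic RNA and development cannot be told apart by this test. The limit also alters the mix of retinal cell types. Age, the difference the design names, stays an open explanation of all of these.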

How the results depend on the processing

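The alternatives with a doublet score under 0.1, under 0.1% mitochondrial UMIs, without cluster 4, with 1 lens sub-class alone and with shares of non-retina nuclei were chosen after seeing the data. Of the values of 6 shares under these and the other alternatives, 26 stayed within the counting interval and 12 moved beyond it. Of the values of 34 list medians 232 stayed, 75 moved and 3 reversed, and of those of 231 gene results 698 stayed, 269 moved and 5 reversed. A minimum of 2000 UMIs moved 0 of 34 list medians and TMM factors moved 1. No paired analysis was possible because each condition was 1 pool. The cause was not tested for the moves below, except that removing nuclei or changing the denominator alters what is counted by construction.

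With predicted doublets kept and the nuclei clustered and named anew, the neural retina-like share was 36.3% in E4, 58.8% in E5 and 1.21% in RET_FGF2, and the lens-like share 3.20% in E4 and 0.686% in E5. In RET_FGF2 over RET the pigment median in RPE-like nuclei was −0.90 and the crystallin median in lens-like nuclei −0.61. With Leiden at resolution 2 the neural retina-like share was 0.321% in RET and 0.629% in RET_FGF2, the lens-like share of E4 3.59%, the pigment median −0.89 and the crystallin median −0.67. At 2000 UMIs the neural retina-like share of RET_FGF2 was 1.17%. With a doublet score under 0.1 that of E5 was 63.9%, the pigment median −0.96 and the crystallin median −0.65. Among non-retina nuclei the lens-like share was 7.22% in E4 and 2.32% in E5.

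In lens epithelium-like nuclei alone, E5 over E4 gave 1.80 for crystallins and 0.53 for lens fiber membrane and cytoskeleton genes, and RET_FGF2 over RET gave 0.72 for FGF and ERK feedback targets, −0.40 for crystallins and, reversed, −0.26 for inflammation genes. In sublibraries 1 to 3 the fiber membrane median of E5 over E4 was −0.0929, the pigment median in RPE-like nuclei of RET_FGF2 over RET −0.92, and the FGF and ERK median 3.28 in ciliary and 1.11 in mesenchyme cluster 2 nuclei. The FGF and ERK median of RET over E4 in RPE-like nuclei reversed there, to −0.10. Sublibraries 4 to 7 gave −1.14 for the pigment median and 2.15 for the ciliary FGF and ERK median. As means over nuclei, E5 over E4 in the retina gave 1.08 for neurogenesis and 0.36 for G2 and M phase genes, and crystallins in the lens gave 0.61 for RET over E4 and −0.69 for RET_FGF2 over RET. Under 0.1% mitochondrial UMIs the neurogenesis median was 0.76 and the G2 and M phase median 0.0839. Without cluster 4, RPE-like nuclei of RET_FGF2 over RET gave −0.0117 for pigment genes, 0.50 for FGF and ERK feedback targets and, reversed, −0.45 for immediate early genes. The same setting gave 0.68 for immediate early genes of RET over E4. The 5 reversed genes were NRG1 (−0.58), ALDH1A1 (−0.30), TBX20 (−0.82), DLL1 (−0.87) and MITF (0.28), all in RPE-like nuclei of RET_FGF2 over RET without cluster 4.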

Other observations

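E5 over E4 in RPE-like nuclei (496 and 539) showed higher Notch pathway genes, at 0.77 [0.56, 0.96] with 6 of 10 higher and 0 lower, BMP targets at 0.42 with 4 of 8 higher, and pigment genes at 0.43 [0.09, 0.63] with 3 of 13 higher. Heat shock and stress chaperones were lower at −0.49, 4 of 11. The extracellular matrix genes ADAMTSL3 and COL8A1 were higher by 3.68 [3.32, 4.09] and 2.83 [2.58, 3.09], the potassium channel gene KCNC1 by 2.03 [1.94, 2.13], and KCNQ3 was lower by −3.42 [−4.65, −2.52], or −2.77 as a mean over nuclei. KCNQ3 is among the 10 leading genes of ciliary cluster 16, and ciliary nuclei were 9.16% of E4 and 4.93% of E5. Whether their RNA brought part of the KCNQ3 counts was not tested. SERPINE3 was higher by 2.19 [2.00, 2.39] at E5, while in RET over E4 it was lower by −4.47 [−5.04, −3.98].

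In the other classes of E5 over E4, wound matrix and adhesion genes were higher in ciliary (1.48, 8 of 13), endothelium-like (1.10, 10 of 14 with 1 lower) and mesenchyme cluster 2 nuclei (0.39, 6 of 14 with 1 lower). Collagens were higher in the same classes, at 0.44, 0.84 and 0.72. Ectoderm-like nuclei had higher Notch pathway genes at 0.52 and lower FGF and ERK feedback targets at −0.48. In RET over E4, ectoderm-like nuclei had higher collagens at 0.48 and pigment genes at 1.58, 7 of 10, while RPE-like nuclei, which pigment genes mark, were 26.3% of RET and 10.6% of E4. Macrophage-like nuclei were 0.296% of E4, 0.463% of E5, 0.739% of RET and 0.606% of RET_FGF2.

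The 4 unnamed clusters held 7.57% of E4, 4.18% of E5, 10.0% of RET and 14.9% of RET_FGF2 nuclei. The 26658 nuclei in 21 wells without a condition carry 3 names given by the authors and were left out.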
